A study of Mus musculus with 9 samples.

How the data were processed

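The series holds 9 RNA-seq libraries of the mouse macrophage line J774A.1, 3 each for a safe control guide, Slc12a9 sgRNA 11 and Slc12a9 sgRNA 15. Samples were grouped by the guide named in their labels. Per the labels' protocols, cells were grown with 10% serum and glutamine, moved to serum-free and glutamine-free medium for 6 h, and lysed, and libraries were made from RNA selected for poly(A) and depleted of ribosomal RNA. The deposited values are counts of reads per gene, which the authors made with STAR and HTSeq on the mm10 genome, per the submitters' processing notes. Versions, gene annotation, strand setting and counting mode are not given in the sources used here. Each deposited table also carries the tallies that HTSeq gives for reads assigned to no gene, and these stayed out of library sizes and tests. Reads assigned to genes were 79.3 to 80.7% of each table, with 4.10 to 4.60% in no feature, 6.32 to 6.56% ambiguous between features, 1.45 to 2.03% of low alignment quality, 0.794 to 1.06% not aligned and 6.20 to 6.69% aligned to more than 1 place. Ambiguous and multiply aligned reads are lost for overlapping genes and close copies, so such genes are undercounted.

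Each table held 55487 gene identifiers, of which 55141 had a symbol in GENCODE M21, an annotation of the same mm10 build, and 346 had none. Gene positions, exon overlaps, GC content and length came from that annotation. A named gene that shared at least 10% of its exon length with another gene is called uncertain. All 1151 entries of the gene lists matched 1 identifier, 8 of them through a synonym.

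Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), library sizes were scaled by TMM (factors 0.979 to 1.02), and a quasi-likelihood model with robust dispersion was fitted to all 9 libraries, which leaves 6 residual degrees of freedom. Tests were 2-sided F tests for sgRNA 11 against safe sgRNA, sgRNA 15 against safe sgRNA, the mean of both guides against safe sgRNA and sgRNA 15 against sgRNA 11, with Benjamini-Hochberg adjustment within each of these 4 contrasts and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistics. CPM values are scaled by TMM and given as mean ± SD of 3 libraries. Principal components were taken from log2 CPM with a prior count of 2. Replicate pairs were checked with a chi-square over genes with at least 20 counts, and no pair agreed within sampling noise.

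Gene lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The test fry was run as an alternative; it asks whether the genes of a list move in a direction and does not compare the list with other genes. Adjustment was over the 37 lists with at least 3 tested members, and for the closing section's further lists over those lists alone. Groups, contrasts, tests, gene lists, the rule for named genes and all but a pair of alternatives were set before the data were examined. Named genes were Slc12a9, then the 12 risen and 12 fallen genes with the largest smaller change of the 2 guides, among genes called in the same direction with both, with a mean of at least 5 CPM and a symbol that is not a predicted model or pseudogene. From each list discussed, up to 4 members with the smallest p for the mean of guides were named, and for sgRNA 15 against sgRNA 11 the 5 higher and 5 lower genes with the largest change under the same minimum. Atf3, Gpnmb in the list of membrane damage, Eef1a1 and CT010467.1, and the genes named in the closing section's further lists, were singled out after their values were seen.

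Alternatives were DESeq2 1.42.0, limma-voom, size factors by relative log expression, no filter on low counts, a minimum mean of 5 CPM, the replicate number as a block, a fit of only the groups compared, a minimum log2 fold change of 1, and each library left out in turn. Scaling by library size only and a correction for GC content and gene length, with spline trends per library removed through offsets for 99.8% of tested genes, were added after seeing the data. Shared controls were simulated 20 times with unchanged groups drawn from the fitted means and dispersions.

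The procedure was tested on simulated data. In a simulated comparison of sgRNA 11 with safe sgRNA over 13453 genes with 200 changed and a planted list of 30 more, the test recovered 53.7% of genes changed 1.2-fold, 89.6% of those changed 1.5-fold and all of those changed 2-fold, and called 10 of 13223 unchanged genes (0.0756%). Of 37 simulated lists it called the planted list and 0 others. Genes were simulated independently of each other, so this cannot show how often correlated genes lead to false list calls. The 200 changed genes were drawn from genes above a minimum mean CPM, so recovery at lower counts was not measured. In this simulation differences of 1.5-fold were thus mostly detectable and those near 1.2-fold often were not. These rates do not carry over to the real comparisons. There 33.5 to 68.0% of tested genes were called, so the adjustment was less strict. Calls between the guides had a median absolute log2 difference of 0.23. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some single genes are withheld and are not reported here.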

Results

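Polyadenylated RNA was sequenced from J774A.1 cells, a mouse macrophage line, that carried either a control guide RNA, called safe in the labels, or 1 of 2 guides against Slc12a9, named sgRNA 11 and sgRNA 15. Slc12a9 belongs to the SLC12 family of cation-chloride cotransporters, and the series concerns its part in the osmolarity of lysosomes, the acidic compartments in which cells break down what they take up. All cells were held for 6 h in serum-free medium without glutamine before RNA extraction. The series asks how expression differs between knockout and control cells in that medium, since glutamine metabolism releases ammonia. Each of the 3 groups had 3 libraries, which makes 9 in all. The gene counts summed to 25613961, 20062072 and 18817850 in the safe libraries, to 22622692, 17617390 and 22167460 with sgRNA 11, and to 20534660, 23521052 and 16405296 with sgRNA 15. The group means were 21497961 ± 3618441, 20802514 ± 2767774 and 20153669 ± 3573144 (SD, n = 3 each), so depth differed by less between groups than within them. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Of 55487 genes, 13453 had enough counts to be tested, and these held 99.9% of the gene counts. The biological coefficient of variation between replicates was 2.82%, and the lowest correlation of log2 CPM (counts scaled to library size) between libraries of a group was 0.993. Counts of safe replicate 1 differed most from those of its group, with chi-square values per degree of freedom of 6.83 and 5.16 against the other two libraries, while replicate pairs as a whole ranged from 1.76 to 6.83. In a principal component analysis, the first component held 59.4% of the variance and set the safe libraries (-42.7 to -40.5) apart from the Slc12a9 guides (17.7 to 24.5). Mitochondrial transcripts took 1.71 ± 0.07% of counts with safe sgRNA, 1.48 ± 0.05% with sgRNA 11 and 1.60 ± 0.01% with sgRNA 15 (SD, n = 3 each). The 10 most abundant genes took 4.92 ± 0.31%, 5.67 ± 0.23% and 5.63 ± 0.06%. Eef1a1, a translation elongation factor, was the most abundant gene in 8 libraries. In safe replicate 1 it was CT010467.1, whose level varied widely between replicates (6894 ± 3281, 8508 ± 2428 and 6620 ± 722 CPM) and did not differ between groups (mean of guides log2 0.12, SE 0.32, edgeR adjusted p = 0.762).

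Neither guide lowered the mRNA of the targeted gene. Slc12a9 (ENSMUSG00000037344, mm10 chromosome 5, 137314558 to 137333597, minus strand) stood at 44.8, 53.5 and 47.0 CPM in the safe libraries, at 62.6, 66.3 and 67.0 with sgRNA 11, and at 48.2, 50.01 and 51.7 with sgRNA 15. Means were 48.4 ± 4.49, 65.3 ± 2.38 and 49.97 ± 1.73 CPM (SD, n = 3 each). In the edgeR quasi-likelihood test Slc12a9 rose with sgRNA 11 (log2 0.43, SE 0.05, adjusted p = 6.46e-13). With sgRNA 15 its log2 difference from safe sgRNA was 0.05 (SE 0.05, adjusted p = 0.426), and the sign of that value turned after a correction for GC content and gene length (-0.07) and without safe replicate 1 (-0.02). The guides differed from each other at this gene (log2 -0.39 for sgRNA 15 against sgRNA 11, SE 0.05, edgeR adjusted p = 2.12e-10). A Cas9 cut need not lower an mRNA, so these counts neither show nor exclude a loss of the protein. The genotype label calls both guides' cells knockdown and the design text calls them knockout. Groups are therefore named by their guide, and every direction given is that of the libraries labelled with it. Genes on the higher-coordinate side of Slc12a9 differed between the guides as well, in a window chosen after its values were seen, near the lower end of which Slc12a9 lies. Over the 40 tested genes between 137309654 and 138810077 on chromosome 5, the median log2 difference of sgRNA 15 against sgRNA 11 was -0.24. The window medians against safe sgRNA were 0.29 with sgRNA 11 and 0.06 with sgRNA 15. The other window of 40 genes that holds Slc12a9, from 136083916 to 137822621, had a median of -0.14 between the guides, 0.09 with sgRNA 11 and -0.01 with sgRNA 15.

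**Figure D1:**
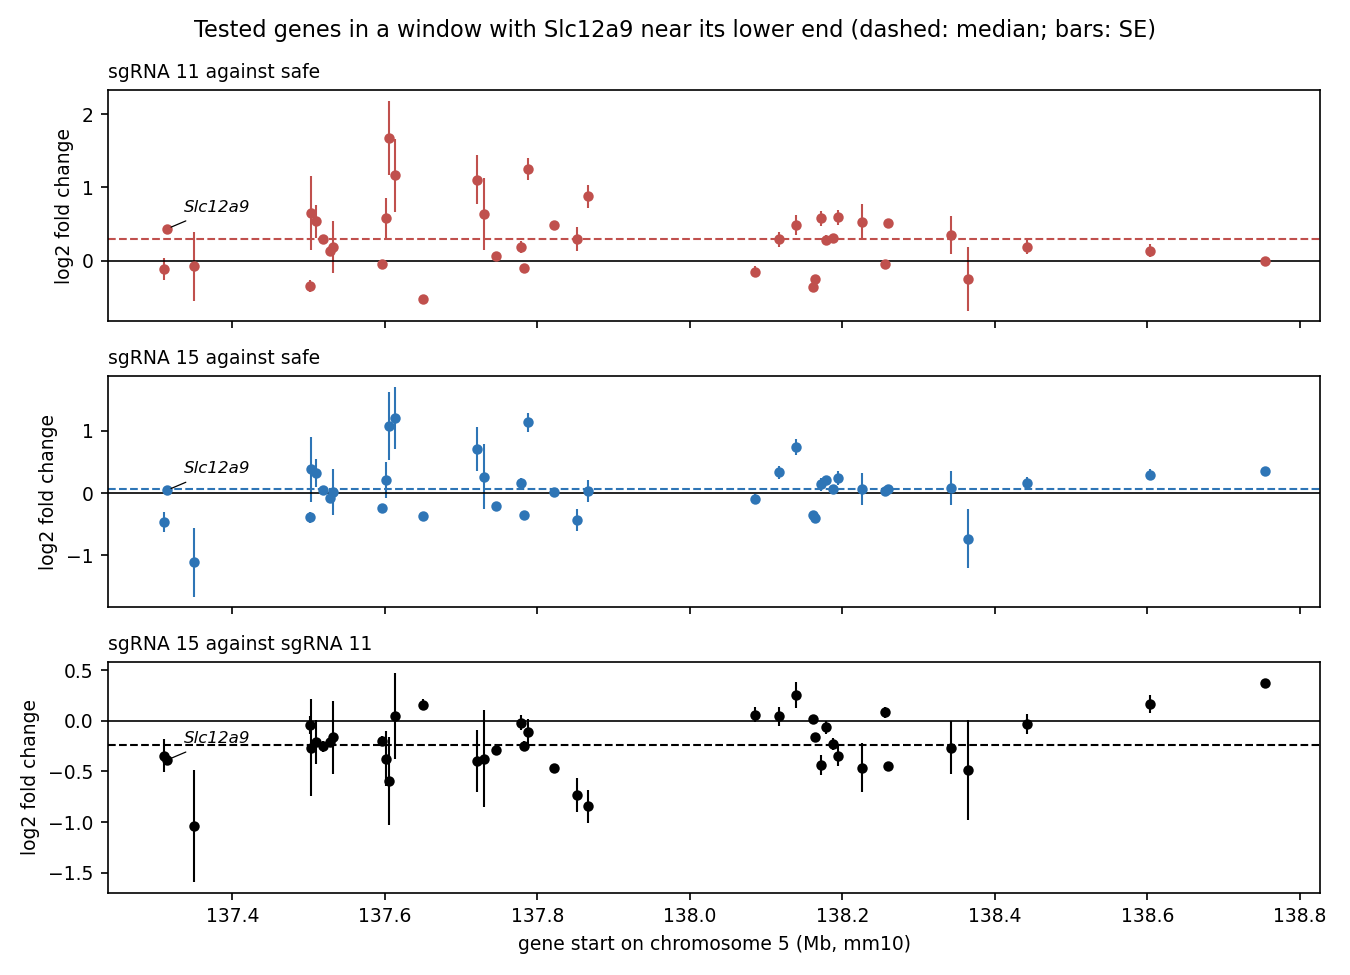
Log2 fold change of the 40 tested genes of the window from 137309654 to 138810077, which has Slc12a9 near its lower end, against their position on mm10 chromosome 5, in panels for sgRNA 11 against safe sgRNA, sgRNA 15 against safe sgRNA and sgRNA 15 against sgRNA 11. Points are genes with the standard error of the edgeR fit, and dashed lines are the window medians of 0.29, 0.06 and -0.24.

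The first comparison, sgRNA 11 against safe sgRNA, asks what differed in cells with the first guide. Genes that ATF4 switches on under amino acid shortage were higher, among them Trib3, a pseudokinase induced by cell stress, which rose 7.83-fold from 34.0 ± 1.28 to 266 ± 4.82 CPM (SD, n = 3). Of the 41 tested genes of that list 38 rose and 1 fell, or 38 and 2 adjusted over the list alone (camera adjusted p = 3.56e-50, and 0.00453 with an estimated correlation). Genes of cholesterol synthesis (27 of 28 fell, or 28 adjusted over the list alone, camera adjusted p = 7.10e-36), of fatty acid synthesis (15 of 18 by either count, camera adjusted p = 2.07e-13) and of inflammation (22 of 27 by either count, camera adjusted p = 2.64e-09) were lower. With an estimated correlation the camera adjusted p of these lists was 0.000869, 0.00444 and 0.00908, in that order. Scd2, a fatty acid desaturase, fell from 1797 ± 8.99 to 587 ± 8.64 CPM, and the chemokine Ccl3 fell from 121 ± 3.65 to 28.8 ± 1.15 CPM. Lysosomal hydrolases were higher (42 of 49 rose and 5 fell by either count, camera adjusted p = 3.86e-10, and 0.0699 with an estimated correlation). Mmp9, a secreted gelatinase, rose from 327 ± 13.98 to 753 ± 14.2 CPM. At an adjusted p under 0.05 in the edgeR quasi-likelihood test, 4484 genes were higher and 4365 lower, 8849 in all or 65.8% of those tested. Most of these changes were small. Their median absolute log2 fold change was 0.43, and 1125 genes (767 higher and 358 lower) changed by at least 1 on the log2 scale.

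With sgRNA 15, the second comparison, ATF4-type genes were again higher (39 of 41 rose over all genes and adjusted over the list alone, camera adjusted p = 3.05e-73, and 0.00363 with an estimated correlation), and Trib3 reached 256 ± 10.1 CPM. Lysosomal hydrolases were higher too (44 of 49 rose and 2 fell by either count, camera adjusted p = 1.84e-20). Ctsb, a lysosomal cysteine protease, rose from 2716 ± 15.0 to 5468 ± 23.5 CPM, and Gpnmb, a transmembrane glycoprotein of the TFEB and MITF list, rose from 25.6 ± 0.48 to 108 ± 0.99 CPM. Lpl, the lipase that releases fatty acids from lipoproteins, fell from 781 ± 19.9 to 233 ± 4.75 CPM. The same edgeR test called 4335 genes higher and 4124 lower, 8459 in all or 62.9%, with a median absolute log2 fold change of 0.40. At least 1 on the log2 scale was reached by 940 of them, 687 higher and 253 lower.

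Most genes called with a guide were called in the same direction with the other. In the edgeR tests of the 2 guides, 3501 genes rose and 3452 fell with both, 6953 in all, a balance that changed with the scaling (2942 and 4179 after the GC and length correction, 3893 and 3105 with library size only). Of the 6953, 639 (496 higher and 143 lower) changed by at least 1 on the log2 scale with each guide. Opposite directions were called for 253 genes. Of the 12 genes that rose most with both guides, 3 belong to the fixed ATF4-type list. Besides Trib3, these were Chac1, a glutathione-degrading enzyme, which rose 5.75-fold with sgRNA 11 and 6.10-fold with sgRNA 15, and Atf5, a stress-induced transcription factor, which rose 5.22-fold and 5.28-fold (64.4 ± 0.68, 336 ± 8.27 and 341 ± 7.38 CPM for safe sgRNA, sgRNA 11 and sgRNA 15). Slc1a4, a transporter of small neutral amino acids, rose 6.46-fold and 6.26-fold (9.24 ± 0.52, 59.4 ± 2.13 and 57.6 ± 0.46 CPM). Aqp9, a channel for water and glycerol, rose 6.32-fold and 6.35-fold. The largest change was that of Pi16, a secreted peptidase inhibitor family member (log2 3.86, SE 0.08, and 3.04, SE 0.08), which stood at 4.48 ± 0.52 CPM with safe sgRNA, 64.7 ± 3.70 with sgRNA 11 and 36.8 ± 1.94 with sgRNA 15. The other risen genes were Klhl33 (log2 3.07 and 2.92), the sterol O-acyltransferase Soat2 (3.11 and 2.87), the ETS transcription factor Etv1 (2.81 and 2.83), Nptxr (3.26 and 2.76), Ypel3 (3.06 and 2.61) and the aspartic protease Ctse (2.81 and 2.38). Part of the exons of Nptxr overlaps a gene on the same strand, so its value is uncertain.

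The 12 genes that fell most with both guides were led by Tnip3. This gene, an inhibitor of NF-kB signalling, fell from 213 ± 3.87 to 43.7 ± 1.69 and 47.6 ± 0.46 CPM (log2 -2.28, SE 0.04, and -2.16, SE 0.04). Dusp2, a phosphatase of MAP kinases, fell by 2.20 and 2.14 on the log2 scale, and Ptger4, a prostaglandin E2 receptor, fell by 1.94 and 2.30. The exons of Ptger4 overlap a gene on the other strand in part, and whether counting used strand is not given, so its value is uncertain. Gadd45b, a stress-response regulator, fell by 2.15 and 1.61, and Traf1, an adaptor of TNF receptors, fell by 1.74 and 1.54. The chemokine Ccl12 fell by 1.79 and 1.47, and Cytip, a regulator of leukocyte adhesion, fell by 1.67 and 1.98. Lpl fell by 1.90 and 1.75 (SE 0.03 each). Pop1, a subunit of RNase P and RNase MRP, fell by 1.80 and 1.56, and the others were Elavl4 (-1.51 and -1.57), Fam72a (-1.39 and -1.39) and Pspc1 (-1.43 and -1.38). All 24 genes kept their direction and an adjusted p under 0.05 with each guide in the alternatives tried.

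**Figure D2:**
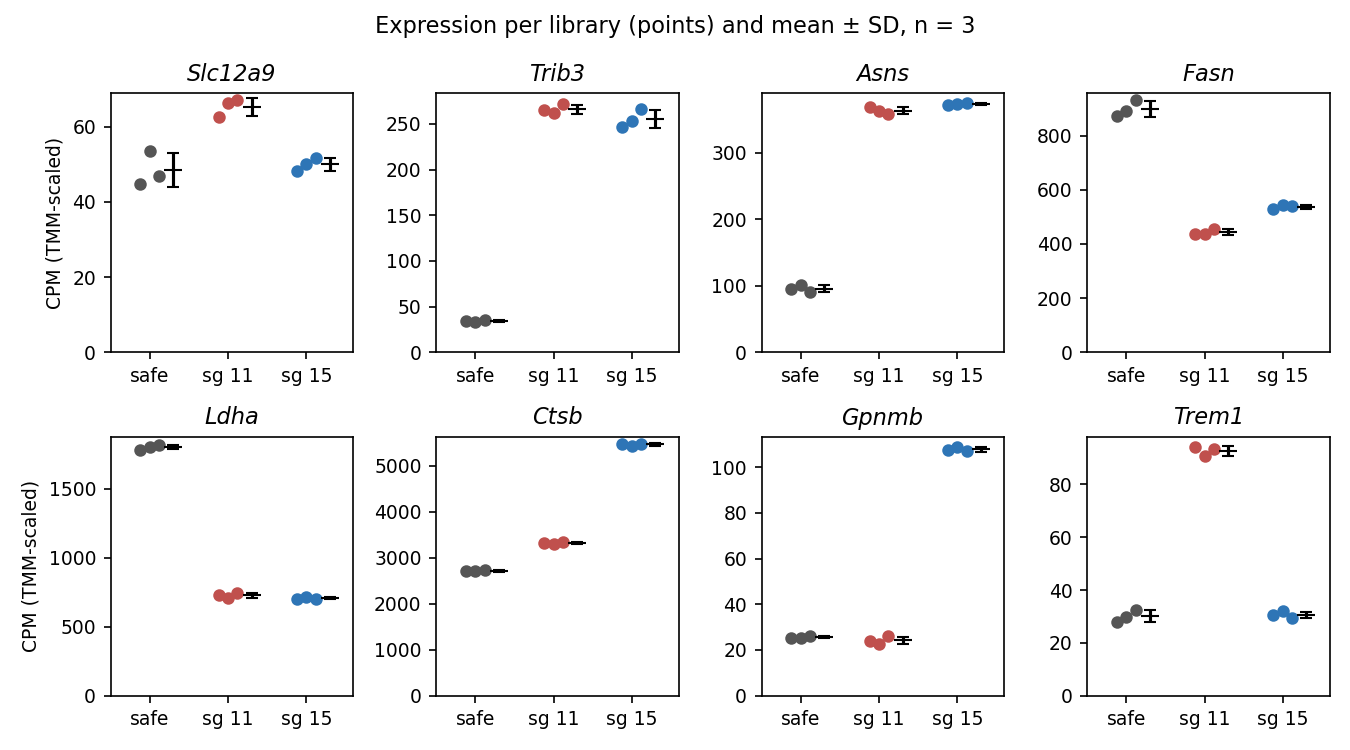
TMM-scaled CPM of 8 named genes in each of the 9 libraries, grouped by safe sgRNA, sgRNA 11 and sgRNA 15. Points are libraries and bars are the mean ± SD (n = 3); Trib3 and Asns were higher with both guides, Fasn and Ldha lower with both, and Gpnmb was higher with sgRNA 15 and Trem1 with sgRNA 11.

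The log2 fold changes of the guides correlated across genes (Pearson r = 0.856, Spearman rho = 0.844), which are not independent replicates. Both comparisons share the 3 safe libraries, and simulated unchanged groups against such controls gave a mean r of 0.501 (0.469 to 0.540 in 20 simulations). The covariance was 0.305 against 0.0184 simulated, a difference of 0.286. Independent lists of these sizes would share 1445 risen and 1338 fallen genes, and simulated unchanged groups shared at most 1. Neither value holds both the effects and the shared controls, and 3 controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls.

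The study's own question, Slc12a9 guides against control, was addressed with the mean of both guides, in which 4672 genes rose and 4475 fell (9147, 68.0% of those tested, edgeR quasi-likelihood test), with 689 and 280 at or above 1 on the log2 scale. The error of this test is the spread between replicates and leaves out differences between the guides. It is thus not a count of genes changed with both guides, which was 6953 in the same direction. Which direction had more genes depended on the scaling, since 3955 rose and 5163 fell after the GC and length correction, and 5091 and 4093 with library size only. For gene groups, 38 lists were fixed beforehand and 37 had enough tested members. The camera test called 21 of them, 10 higher and 11 lower, and 11 of these calls held with an estimated correlation. Counts adjusted over the list alone equalled those over all genes for 33 of the 37 lists, and the others are given with their list. The list's median, mean and test differed in sign for 2 lists, hypoxia-responsive genes and alternative activation. Some lists share members, so their values are not independent. Among genes named below under other lists, Gpt2, Herpud1, Slc7a11, Ddit4 and Sesn2 also belong to the ATF4-type list. Fads2 and Insig1 belong to both the cholesterol and the fatty acid lists.

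Genes of the amino acid and integrated stress response, which ATF4 drives, rose together. Of 41 tested members 38 rose, 1 fell and 2 were not called, with a median log2 fold change of 0.94 (0.86 with sgRNA 11 and 0.97 with sgRNA 15, camera adjusted p = 6.70e-60 for the mean of guides). With an estimated correlation the camera adjusted p was 0.00362 for the mean of guides, 0.00453 with sgRNA 11 and 0.00363 with sgRNA 15. Asns, which makes asparagine from glutamine, rose 3.86-fold (log2 1.95, SE 0.03) from 95.3 ± 5.23 to 364 ± 5.51 and 374 ± 1.46 CPM. Cth, which makes cysteine by transsulfuration, rose 4.28-fold (log2 2.10, SE 0.03). Atf3, a stress-induced transcription factor, was the member that fell (log2 -1.17, SE 0.03), from 166 ± 3.31 to 45.5 ± 3.61 and 119 ± 2.70 CPM. The glutamine, ammonia and urea list as a whole was not called (10 of 31 members rose, 15 fell, median log2 -0.11, camera adjusted p = 0.488). Within it Gpt2, a mitochondrial alanine transaminase, rose 3.48-fold from 24.3 ± 0.99 to 84.2 ± 1.09 and 84.5 ± 0.65 CPM. Odc1, which makes the polyamine putrescine, fell by 1.00 on the log2 scale (SE 0.03), and Cad, which starts pyrimidine synthesis from glutamine, fell by 0.71 (SE 0.02). The unfolded protein response of the endoplasmic reticulum was not called either (9 of 32 rose, 17 fell, median -0.10, camera adjusted p = 0.242). In that list Herpud1 (log2 1.03) and Sel1l (0.67), which act in the removal of misfolded proteins, rose, and the chaperones Pdia3 (-0.55) and Hsp90b1 (-0.61) fell.

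All 28 tested genes of cholesterol synthesis and the SREBP2 response fell, with a median log2 fold change of -0.82 (-1.08 with sgRNA 11 and -0.58 with sgRNA 15, camera adjusted p = 9.50e-28). Tmem97 (log2 -1.22, SE 0.03) fell from 136 ± 2.80 to 52.8 ± 1.38 and 64.4 ± 1.87 CPM, and the desaturase Fads2 (-1.04, SE 0.03) fell as well. Of 18 genes of fatty acid synthesis and the SREBP1 response, 15 fell and 2 rose (median -0.62, camera adjusted p = 1.67e-10). Scd2 fell by 1.22 on the log2 scale (SE 0.02), Fasn, the fatty acid synthase, by 0.88 (SE 0.02), and Insig1, which holds SREBPs in the endoplasmic reticulum, by 1.04 (SE 0.03). Genes of the LXR response and cholesterol efflux (9 of 14 rose, 4 fell, median 0.24, camera adjusted p = 0.640) and of the PPARG response and lipid storage (9 of 21 rose, 8 fell, median -0.02, adjusted p = 0.488) were not called as lists. In these Lpl fell, while Arl4c (log2 1.03), Smpdl3a (1.29), the lysosomal cholesterol carrier Npc2 (0.37), the transcription factor Klf4 (1.79) and the cholesterol esterifying enzyme Soat1 (0.49) rose. Fabp5, a fatty acid carrier, fell from 76.8 ± 0.27 to 24.4 ± 1.02 and 55.4 ± 2.68 CPM.

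Lysosomal hydrolases and their cofactors rose in 44 of 49 tested members and fell in 5 (median log2 0.37, camera adjusted p = 4.34e-15, adjusted p = 0.0390 with an estimated correlation). The list rose with each guide. With sgRNA 11, 42 members rose and 5 fell (median 0.31, camera adjusted p = 3.86e-10). With sgRNA 15, 44 rose and 2 fell (median 0.40, camera adjusted p = 1.84e-20). With an estimated correlation the list was called with sgRNA 15 (camera adjusted p = 0.0193) but not with sgRNA 11 (camera adjusted p = 0.0699). Sgsh, which degrades heparan sulfate, rose 2.65-fold (log2 1.41, SE 0.04). Ctsd, an aspartic protease, rose from 1360 ± 10.8 to 2060 ± 66.4 and 3032 ± 45.3 CPM. Ctsb rose 1.22-fold with sgRNA 11 and 2.01-fold with sgRNA 15, and Hexa, a subunit of beta-hexosaminidase, rose 1.59-fold and 1.92-fold. Sgsh, Ctsd, Hexa and Ctsb share part of their exons with other gene models, so their values are uncertain. TFEB, TFE3 and MITF with their responsive genes rose in 17 of 22 members and fell in 3 (median 0.26, camera adjusted p = 2.99e-08, adjusted p = 0.0390 with an estimated correlation). Of its members 17 rose and 4 fell with sgRNA 15 (median 0.50, camera adjusted p = 2.15e-17, and 0.0124 with an estimated correlation). With sgRNA 11, 10 rose and 5 fell (median 0.07, camera adjusted p = 0.00287), a call that was lost at adjusted p = 0.142 with an estimated correlation. This list shares members with the hydrolase (Ctsd and Ctsa among them), autophagy (Sqstm1), ion channel (Mcoln1) and ATF4-type (Trib3) lists. Its call is thus not independent of theirs. The autophagy list rose in 27 of 40 members and fell in 7 (median 0.26, camera adjusted p = 9.20e-05). Sqstm1, a receptor for ubiquitin-marked cargo, rose from 337 ± 6.42 to 669 ± 2.40 and 870 ± 8.39 CPM. Tecpr1, which acts where autophagosomes meet lysosomes, rose 1.58-fold with sgRNA 11 and 3.89-fold with sgRNA 15, Calcoco1, an autophagy receptor, rose 2.54-fold with the mean of guides, and Map1lc3b, which coats autophagosomes, rose 1.52-fold. Lysosomal membrane proteins and transporters rose in 25 of 37 members and fell in 5 (median 0.37, camera adjusted p = 0.000465), a call that was lost at adjusted p = 0.102 with an estimated correlation. Slc17a5, the sialic acid exporter, rose (log2 0.69), as did Mfsd1 (0.41) and the iron exporter Slc40a1 (0.63), and Slc15a3, a peptide and histidine transporter, fell (-0.53). Lysosomal and endosomal ion channels and exchangers rose in 18 of 27 members and fell in 2, or 19 and 2 adjusted over the list alone (median 0.20, camera adjusted p = 0.00175), and this call was lost at adjusted p = 0.0700 with an estimated correlation. The sodium-proton exchanger Slc9a9 rose 2.71-fold (log2 1.44, SE 0.05), the potassium and proton channel Tmem175 2.06-fold, the calcium channel Mcoln1 1.68-fold and the chloride-proton exchanger Clcn7 1.53-fold.

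The subunits of the V-ATPase, the proton pump of lysosomes, were not called for the mean of guides (10 of 17 rose, 4 fell, median log2 0.14, camera adjusted p = 0.163). Atp6v1a (log2 0.65) and Atp6ap1 (0.40) rose, and Atp6v1h (-0.42) and Atp6v1b2 (-0.27) fell. Of the SLC12 family and its kinases 3 of 10 members rose and 4 fell (median 0.04, camera adjusted p = 0.806), and the sign of that median turned under 6 of 16 alternatives, the GC and length correction among them (-0.08). Slc12a5, a potassium-chloride exporter, rose from 33.8 ± 0.85 to 79.5 ± 2.45 and 47.8 ± 2.36 CPM. Slc12a2, which imports sodium, potassium and chloride, fell by 0.40 on the log2 scale (SE 0.04), and Oxsr1, a kinase that acts on these transporters, fell by 0.56 (SE 0.03). Genes of the osmotic stress response, of the kind that NFAT5 drives, fell in 12 of 17 members and rose in 4 (median -0.33, camera adjusted p = 0.00519). That call was lost at adjusted p = 0.0524 with an estimated correlation and at 0.0700 when only genes of at least 5 CPM were tested. The members with the smallest p were Ccl2, a chemokine for monocytes (log2 -1.80), Tnfrsf9, a co-stimulatory receptor (-2.52), and Akr1b3, the aldose reductase that makes the osmolyte sorbitol (-0.42), which fell, and the amino acid transporter Slc38a2 (0.48), which rose. Of these, Ccl2 also belongs to the NF-kB list and Slc38a2 to the ATF4-type list. Genes of endolysosomal damage and membrane repair were not called (15 of 34 rose, 6 fell, median 0.03, camera adjusted p = 0.334), although Lgals3, a galectin that binds damaged lysosomes, rose (0.60), as did Osbpl9 (0.81), and the segregase Vcp fell (-0.59). Gpnmb of this list rose with sgRNA 15 (2.07) and not with sgRNA 11 (-0.08, edgeR adjusted p = 0.253).

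Glycolytic genes fell in 18 of 26 members and rose in 3 (median log2 -0.42, camera adjusted p = 1.50e-11). Ldha, which makes lactate, fell from 1803 ± 17.2 to 727 ± 20.4 and 707 ± 8.62 CPM. Slc16a1, a lactate carrier, fell by 1.46 on the log2 scale (SE 0.03), the triosephosphate isomerase Tpi1 by 1.01 (SE 0.02) and the pyruvate kinase Pkm by 0.71 (SE 0.02). Nuclear-encoded genes of oxidative phosphorylation fell in 32 of 48 members and rose in 8 (median -0.16, camera adjusted p = 0.00258), a call that was lost at adjusted p = 0.319 with an estimated correlation. The electron carrier cytochrome c, Cycs, fell by 0.96, Atp5g3 by 0.79, Sdhd by 0.49 and Cyc1 by 0.43. The NRF2-type antioxidant list fell in 17 of 27 members and rose in 7, or 17 and 8 adjusted over the list alone (median -0.18, camera adjusted p = 0.00760, adjusted p = 0.147 with an estimated correlation). Its named members split, since Txn1 (-0.69), Gsr (-0.65) and Txnrd1 (-0.54) of the thioredoxin and glutathione systems fell, whereas Slc7a11, the cystine importer, rose from 6.69 ± 1.06 to 23.8 ± 0.87 and 31.5 ± 2.47 CPM. Slc7a11 is also a member of the ATF4-type list. Hypoxia-responsive genes were not called (8 of 23 rose and 11 fell, or 9 and 11 adjusted over the list alone, median -0.14 but mean 0.001, camera adjusted p = 0.780), with a fall of the glucose carrier Slc2a1 (-0.88) and of Pdk1 (-0.56), which restrains pyruvate entry into mitochondria, and a rise of Ddit4 (1.59), an inhibitor of mTORC1, and Ero1l (0.57). Iron handling genes were not called (5 of 21 rose, 11 fell, median -0.14, camera adjusted p = 0.220). Tfrc, the receptor for transferrin-bound iron, fell from 381 ± 12.2 to 180 ± 6.99 and 242 ± 2.47 CPM, Slc11a2, an iron importer, fell by 0.39, and the ferritin heavy chain Fth1 rose (log2 0.32).

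Genes of NF-kB and inflammatory cytokines fell in 24 of 27 members, and Tnfaip2 (log2 0.97) was the member that rose (median -0.67, camera adjusted p = 2.01e-09). Ccl2 fell from 152 ± 7.78 to 32.2 ± 2.35 and 58.6 ± 0.83 CPM, and Ccl3 and Ccl4, chemokines for leukocytes, fell by 1.48 and 1.57 on the log2 scale (SE 0.04 and 0.04). Macrophage identity genes and phagocytic receptors rose in 26 of 35 members and fell in 5 (median 0.34, camera adjusted p = 3.34e-09, adjusted p = 0.0390 with an estimated correlation, 0.0296 with sgRNA 11 and 0.0604 with sgRNA 15). Fcgr2b, the inhibitory IgG receptor, rose from 144 ± 3.46 to 378 ± 4.85 and 561 ± 7.87 CPM, the activating IgG receptor Fcgr3 rose 2.02-fold and the lipid-sensing receptor Trem2 1.62-fold. Antigen presentation by MHC rose in 12 of 22 members and fell in 2 (median 0.24, camera adjusted p = 0.0202), but the call was lost at adjusted p = 0.102 with an estimated correlation and at 0.0574 after the GC and length correction. The list was called with sgRNA 11 (16 rose and 2 fell, median 0.42, camera adjusted p = 0.000644) and not with sgRNA 15 (10 rose and 4 fell, median 0.13, camera adjusted p = 0.355). Cd86, a co-stimulator of T cells, rose 2.68-fold, and the peptide-loading genes Tap1 (log2 0.53), Tap2 (0.48) and Tapbp (0.30) rose. Interferon-stimulated genes were not called (12 of 43 rose, 19 fell, median -0.06, camera adjusted p = 0.966). Oas1g (1.26) and Gbp2 (1.60) rose, Rsad2 (-1.50) and Cxcl10 (-2.14) fell, and the sign of the list's median turned when only genes of at least 5 CPM were tested (0.01). Cxcl10 was low, at 2.48 to 3.35 CPM with safe sgRNA and 0.53 to 0.82 with the guides, and Gbp2 stood at 1.47 to 2.16 CPM with safe sgRNA. Alternative activation was not called (4 of 12 rose and 3 fell, or 3 and 3 adjusted over the list alone, median 0.09 but mean -0.10, camera adjusted p = 0.488), with the matrix protein Fn1 (1.27) and Mgl2 (0.26) higher and Clec7a (-0.58) and Il10 (-2.78) lower. Il10 was near the floor, at 0.71 to 1.16 CPM with safe sgRNA and 0 to 0.27 with the guides. Osteoclast and giant cell genes were not called (2 of 11 rose, 6 fell, median -0.37, camera adjusted p = 0.102), though they were with sgRNA 15 alone (median -0.54, camera adjusted p = 0.0106, lost at adjusted p = 0.0606 with an estimated correlation), and among them the carbonic anhydrase Car2 (-1.28) and Fos (-0.99) fell and Nfatc1 (0.57) rose, while Mmp9 rose 2.30-fold with sgRNA 11 and fell with sgRNA 15 (log2 -0.22). Matrix, protease and adhesion genes rose in 9 of 25 members and fell in 10 (median 0.005, mean 0.23, camera adjusted p = 0.0244), with medians of -0.06 with sgRNA 11 and 0.06 with sgRNA 15. That call was lost at adjusted p = 0.102 with an estimated correlation and at 0.210 with the replicate number as a block, and the sign of the median turned under 9 of 16 alternatives, among them size factors by relative log expression (-0.004) and the GC and length correction (-0.03). The integrins Itgal (1.36) and Itgb5 (1.44) rose.

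Genes of S phase and DNA replication fell in 30 of 36 members and rose in 2 (median log2 -0.31, camera adjusted p = 4.35e-07). Mcm3 (-0.53) and Mcm4 (-0.57) of the replicative helicase and both ribonucleotide reductase subunits, Rrm1 (-0.54) and Rrm2 (-0.57), fell. Genes of G2 and mitosis fell in 32 of 38 members and rose in 5 (median -0.30, camera adjusted p = 4.83e-06), a call that was lost at adjusted p = 0.0783 with an estimated correlation. The anaphase activator Cdc20 fell from 202 ± 8.71 to 117 ± 2.33 and 118 ± 1.82 CPM, and Ccnb1 (-0.56), Aurka (-0.56) and Bub1 (-0.52) fell as well. Heat shock and cytosolic chaperone genes fell in 15 of 18 members and rose in 1 (median -0.58, camera adjusted p = 6.51e-16). Hsp90aa1, an inducible HSP90, fell from 1022 ± 33.3 to 362 ± 10.0 and 478 ± 4.85 CPM, and the mitochondrial chaperonin Hspd1 fell by 1.05, Hspa4 by 0.83 and the cochaperone Fkbp4 by 0.79 on the log2 scale (SE 0.02 each). Immediate-early and serum-response genes fell in 17 of 29 members and rose in 5 (median -0.24, camera adjusted p = 0.00964, adjusted p = 0.0700 with an estimated correlation), with Srf, the serum response factor, lower (-1.01) and Dusp6 (1.00) and Klf4 higher. p53-responsive genes were not called (14 of 29 rose, 11 fell, median 0.03, camera adjusted p = 0.373), and the sign of that median turned with the GC and length correction (-0.02). The pro-apoptotic Bbc3 (1.81), the stress sensor Sesn2 (1.66) and the cell cycle inhibitor Cdkn1a (0.58) rose, and the kinase Plk2 fell from 197 ± 4.21 to 34.8 ± 2.26 and 98.96 ± 1.38 CPM. Cytosolic ribosomal protein genes rose in 44 of 55 members and fell in 2 (median 0.20, camera adjusted p = 4.65e-05), a call that was lost at adjusted p = 0.418 with an estimated correlation. Rps18 (0.40), Rps4x (0.34) and Rps12 (0.32) rose.

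**Figure D3:**
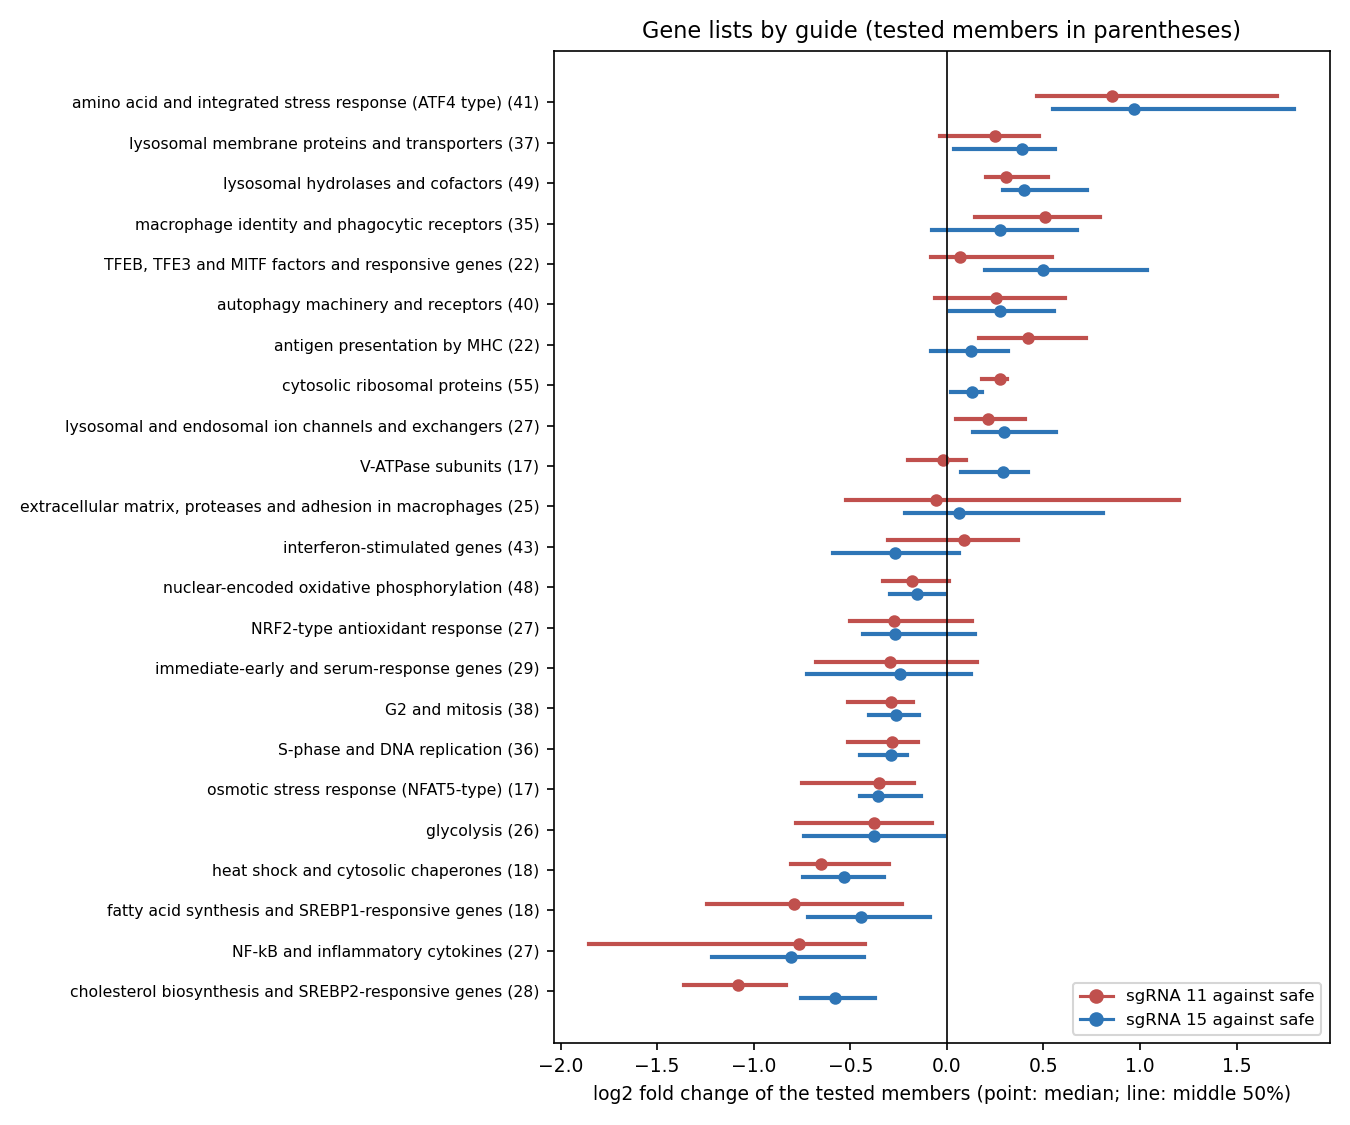
Median log2 fold change against safe sgRNA (points) and middle 50% of members (lines) of 23 gene lists, with a point for each guide. The ATF4-type list lies highest (0.86 with sgRNA 11 and 0.97 with sgRNA 15), and the cholesterol list lies lower with sgRNA 11 (-1.08) than with sgRNA 15 (-0.58).

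Markers of RNA quality and of other cells were measured beside these lists. Mitochondrially encoded mRNAs were not called as a list (3 of 13 rose, 6 fell, median log2 -0.11, camera adjusted p = 0.419), and the sign of that median turned with the GC and length correction (0.01). Members moved apart, since mt-Nd1 fell from 2945 ± 189 to 1563 ± 40.9 and 1661 ± 11.0 CPM, mt-Nd2 (-0.28) and mt-Nd3 (-1.33) fell and mt-Nd4 rose (0.23). The level of mt-Nd3 was near the floor, at 1.26 to 1.67 CPM with safe sgRNA and 0.36 to 0.89 with the guides. Long nuclear noncoding RNAs were not called (6 of 9 rose, 2 fell, median 0.20, camera adjusted p = 0.488), with Neat1 (0.50), Xist (0.20) and 2900097C17Rik (0.20) higher and Snhg1 (-0.64) lower. Of 21 mesenchymal and epithelial markers only 4 had enough counts to be tested, and the list was not called (2 rose, 1 fell, median 0.24, camera adjusted p = 0.838). Their levels were low. Pdgfra rose from 1.34 ± 0.29 to 2.16 ± 0.33 and 2.18 ± 0.32 CPM, Acta2 (log2 1.04) rose and Cdh5 (-0.50) fell, though Cdh5 was not called with sgRNA 11 alone (-0.40, edgeR adjusted p = 0.112). These calls were lost for Acta2 without safe replicate 2 (0.64, edgeR adjusted p = 0.132) and for Cdh5 without safe replicate 1 (-0.46, edgeR adjusted p = 0.0760), and Pecam1 was not called (-0.20, edgeR adjusted p = 0.588) and turned sign without safe replicate 1 (0.08). Of the 30 markers listed for lymphoid, neutrophil, mast, erythroid and dendritic cells, S100a8 alone was tested and rose (0.59, edgeR adjusted p = 0.00119), and this call was lost without safe replicate 2 (0.38, edgeR adjusted p = 0.0585). Reads that aligned to more than 1 place were left out of the gene counts, so genes with close copies, among them Oas1g, Fcgr2b and Fcgr3, Ccl3 and Ccl4, Ldha, Tpi1, Fth1, Hsp90aa1 and the ribosomal protein genes, are uncertain to that extent. Overlapping exons leave Slc15a3, Tmem175, Sqstm1, Hsp90b1, Pkm, Tapbp, Tap2, Rps12, Snhg1 and Xist uncertain as well.

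The last comparison set sgRNA 15 directly against sgRNA 11, to ask where the guides differed. Genes of cholesterol synthesis (25 of 28 tested), fatty acid synthesis (14 of 18), the V-ATPase (15 of 17) and the TFEB response (15 of 22) were higher with sgRNA 15 than with sgRNA 11, and interferon-stimulated (24 of 43), MHC (15 of 22) and osteoclast genes (6 of 11) were lower. For cholesterol and fatty acid synthesis this was a smaller fall against safe sgRNA. Their medians were -0.58 and -0.44 with sgRNA 15, and -1.08 and -0.79 with sgRNA 11. Gpnmb stood at 108 ± 0.99 CPM with sgRNA 15 against 24.2 ± 1.64 with sgRNA 11 and 25.6 ± 0.48 with safe sgRNA (log2 2.15 between the guides, SE 0.05, edgeR adjusted p = 5.33e-55). Trem1, a receptor that amplifies inflammation, stood at 30.6 ± 1.21, 92.7 ± 1.85 and 30.02 ± 2.31 CPM (log2 -1.59, SE 0.05, edgeR adjusted p = 1.70e-45). Higher with sgRNA 15 were also Zfp469, annotated as a long noncoding RNA (log2 2.28, SE 0.12), the aminopeptidase Anpep (2.05), the macrophage elastase Mmp12 (1.93) and Tenm4 (1.91). Lower were the kinase Dmpk (-1.55), Mmp9 (-1.42), the ephrin receptor Epha2 (-1.33) and the pro-apoptotic Bmf (-1.31). Zfp469 and Mmp12 fell with sgRNA 11 (-1.52 and -1.40) and rose with sgRNA 15 (0.76 and 0.53), and Dmpk and Mmp9 did the reverse (1.72-fold and 2.30-fold higher with sgRNA 11, log2 -0.77 and -0.22 with sgRNA 15). The edgeR quasi-likelihood test called 2416 genes higher and 2086 lower with sgRNA 15, 4502 in all or 33.5%, with a median absolute log2 difference of 0.23 and 180 genes at or above 1. Which direction had more genes depended on the processing. It was 1928 higher and 2000 lower after the GC and length correction, 2020 and 2120 with no filter on low counts, and 2123 and 2196 with a minimum mean of 5 CPM. Of these 4502, 2530 had changed in the same direction with both guides, and all 253 genes of opposite direction were among the calls.

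Of the lists, 21 were called between the guides, 15 higher and 6 lower with sgRNA 15, and 7 of these calls held with an estimated correlation. Counts adjusted over the list alone equalled those over all genes for 15 of 37 lists. In cholesterol synthesis 25 of 28 genes were higher and none lower with sgRNA 15, over all genes and adjusted over the list alone (median log2 0.50, camera adjusted p = 3.57e-29). In the fatty acid list 14 of 18 were higher and none lower by either count (0.32, camera adjusted p = 7.99e-12). In the V-ATPase 15 of 17 subunits were higher and none lower by either count (0.31, camera adjusted p = 3.70e-15), and the list's median against safe sgRNA was 0.29 with sgRNA 15 (camera adjusted p = 0.000327, a call that was lost at adjusted p = 0.0509 with an estimated correlation) and -0.02 with sgRNA 11 (camera adjusted p = 0.733). Atp6v1a rose 2.04-fold with sgRNA 15 and 1.21-fold with sgRNA 11. In the TFEB list 15 of 22 genes were higher and 4 lower, or 15 and 5 adjusted over the list alone (0.22, camera adjusted p = 1.42e-21). Interferon-stimulated genes were lower in 24 of 43 and higher in 1, or 27 and 1 adjusted over the list alone (-0.32, camera adjusted p = 1.66e-06). MHC genes were lower in 15 of 22 and higher in none, or 18 and none adjusted over the list alone (-0.26, camera adjusted p = 8.29e-08), and osteoclast genes were lower in 6 of 11 and higher in 2, or 6 and 3 adjusted over the list alone (-0.16, camera adjusted p = 0.000166). The calls of macrophage identity genes (-0.19, lower in 21 of 35, camera adjusted p = 9.51e-09), ribosomal protein genes (-0.14, lower in 47 of 55, camera adjusted p = 1.87e-09) and lysosomal hydrolases (0.13, higher in 24 of 49, camera adjusted p = 2.19e-05) were lost at adjusted p = 0.0510, 0.232 and 0.111 with an estimated correlation. The differences between the guides correlated with GC content across genes (Spearman rho = -0.29). After a correction for GC content and gene length, 73.1% of the 4502 genes were still called in the same direction, and 19 of the 21 list calls were.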

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

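The tests of GC content and gene length, of shared safe libraries, of a weaker copy between the guides, and of the Slc12a9 neighbourhood were chosen only after the results were seen. Results are listed because the direct test of sgRNA 15 against sgRNA 11 found a difference, and groups of 3 libraries were too small for an outlier test.

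Opposite directions with the guides were called for 253 genes. The log2 difference of sgRNA 15 against sgRNA 11 was 2.28 for Zfp469, 2.15 for Gpnmb, 2.05 for Anpep, 1.93 for Mmp12 and 1.91 for Tenm4. It was -1.59 for Trem1, -1.55 for Dmpk, -1.42 for Mmp9, -1.33 for Epha2 and -1.31 for Bmf. Among the lists, the median difference was 0.31 for V-ATPase subunits, 0.22 for TFEB, TFE3 and MITF factors and responsive genes, 0.50 for cholesterol synthesis, 0.32 for fatty acid synthesis, -0.32 for interferon-stimulated genes, -0.26 for antigen presentation by MHC and -0.16 for osteoclast genes.

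Both guides shared a broad change of expression. Noise between the shared safe replicates alone does not account for it. The covariance of the guides' log2 fold changes was 0.305 against 0.0168 to 0.0211 in simulated unchanged groups. Those simulations hold only the spread between replicates, so they cannot exclude a deviation common to all safe libraries. GC content and gene length do not account for it either, since 90.5% of the 9147 genes called for the mean of guides were still called in the same direction after correction. Of 100 splits of the 9 libraries, 1, the real split, gave as many genes for the mean of guides (9147, highest other 7643). For genes called with both guides 1 split, the real one, gave as many (6953, highest other 6113). The highest other split kept the 3 safe libraries together and mixed the guides. The splits thus show that libraries grouped by their labels. They cannot tell a chance difference between cell populations from an effect of the guides, since the replicates may be technical. For each guide alone the splits were too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes with sgRNA 11 (8849, highest other 0) and 1 of 10 with sgRNA 15 (8459, highest other 0). A loss of Slc12a9 shared by both guides may account for the change, as a hypothesis, but a difference between the safe and the Slc12a9 cells that arose in culture or in handling remains open and untested, because the labels name no separate cultures and the mRNA of Slc12a9 was not lowered.

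The guides also differed from each other. A weaker copy of a single change, scaled alike in every gene, is argued against as the whole difference by the 253 genes called in opposite directions. Simulations of such a copy, scaled by the slope of 0.804, gave 0. A weaker copy together with a bias by GC content was not simulated. Of the 4502 genes called between the guides, 2530 had changed in the same direction with both. How much of the difference a weaker copy accounts for thus remains open. After correction for GC content and gene length 73.1% of the 4502 genes were still called in the same direction, short of the 80% set as the bound. For the rest this bias cannot be told apart from a true difference. In all 3928 genes were called between the guides after correction, and 1 of the 4502 calls turned, which argues against this bias as the whole cause. Too few splits exist for a share under 0.05 here, and 1 of 10, the real one, gave as many genes (4502, highest other 1). Unequal loss of Slc12a9, effects of a guide at other sites and drift between the cell populations may each contribute, and none of these was tested.

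Genes on the higher-coordinate side of Slc12a9 were higher with sgRNA 11 than with sgRNA 15. Of 640 windows of 40 genes 2 hold Slc12a9. The window from 137309654 to 138810077 on chromosome 5 had the largest absolute median difference (-0.24, permutation p = 0.001, the smallest that 1000 shuffles of gene order can give), and Slc12a9 lies near its lower end. The shuffles used uncorrected differences and treated neighbouring genes as unrelated. This p thus cannot separate an effect at Slc12a9 from traits that neighbours share, such as GC content. The other, from 136083916 to 137822621, ranked 17 (-0.14), so the difference was smaller where the lower-coordinate side was included. A bias by GC content and length is argued against as the whole cause, since the medians after correction were -0.19, still the largest, and -0.10, where 95% of windows lay between -0.084 and 0.086. Whether the first window moved evenly, as after a change in copy number near a Cas9 cut, cannot be told apart from changes of single genes, since 77.5% of the 40 genes were lower with sgRNA 15 and their SD of 0.29 was above the lower quartile over windows of 0.247. Against safe sgRNA the medians with sgRNA 11 ranked 10 (0.29) and 289 (0.09) of 640. Whether the rise of Slc12a9 mRNA with sgRNA 11 is part of a regional difference remains open, and DNA data would have to test it.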

How the results depend on the processing

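Scaling by library size only and the GC and length correction were chosen after seeing the data, and all other alternatives before. Counts of called genes stayed within 1.5 times of the reported ones under every alternative but the minimum log2 fold change of 1, which by construction left 1125 genes for sgRNA 11, 940 for sgRNA 15, 969 for the mean of guides, 180 between the guides and 639 with both guides. The balance of risen and fallen genes did depend on the scaling: risen genes made up 51.1% of calls for the mean of guides, 43.4% after the GC and length correction and 55.4% with library size only, and 27 of the 9147 calls were called in the other direction after that correction. DESeq2 called 8565 genes for the mean of guides and limma-voom 9099. Leaving out 1 library gave 8402 to 8903 genes for sgRNA 11, 7957 to 8556 for sgRNA 15, 8576 to 9156 for the mean, 3872 to 4581 between the guides and 6540 to 6815 with both guides, and a correlation of the guides of 0.828 to 0.861; without safe replicate 1, which stood apart, the mean gave 8621. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.008 to 0.058, and 5 of 9 libraries matched their own number best. With the replicate block the mean gave 9236 genes, and the call of the matrix and adhesion list alone was lost. The sign turned for Slc12a9 with sgRNA 15 after the GC and length correction (-0.072) and when libraries were left out (-0.016 to 0.11), and for Pecam1, at under 1 CPM, when libraries were left out (-0.44 to 0.084); neither was called, and the cause was not tested. Of 3415 alternative values of 198 results for named genes 3409 kept direction and side of the threshold, 3 were weaker (Acta2, Cdh5 and S100a8, all at low counts) and 3 turned. For lists, direction means that of the test and not the sign of the median. Of 591 alternative values of 37 lists 559 kept direction and side, 13 were weaker (10 with an estimated correlation), 13 stronger (with fry) and 6, none of them called, turned. The sign of the median turned in 22 of the 591, in 7 lists, of which only the matrix and adhesion list was called. Depth limits genes of low counts most. Of 55487 genes, 42034 had too few counts to be tested, but only 18824 to 20104 had any count in a given library. The number of untested genes is thus no measure of depth alone.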

Other observations

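The following lists were chosen after the values of single genes were seen, so they are no independent evidence of a direction, and no explanation was tested. Genes of ribosome biogenesis were lower with both guides. Of 49 tested genes of ribosome biogenesis and the nucleolus 48 fell and only Polr1c rose (log2 0.18), with a median log2 fold change of -0.68 for the mean of guides (camera adjusted p = 9.42e-40, and 0.00135 with an estimated correlation). Ncl, a major nucleolar protein, fell by 1.17, the rRNA methyltransferase Nop2 by 1.15 and Nolc1 by 1.01 on the log2 scale. The fall was smaller with sgRNA 15 than with sgRNA 11 (median difference 0.13, camera adjusted p = 0.000363). Cytosolic ribosomal protein genes had moved the other way (median 0.20), a call that was lost at adjusted p = 0.418 with an estimated correlation. Translation initiation and elongation factors fell in 18 of 25 genes and rose in 6 (median -0.45, camera adjusted p = 5.80e-07). Eif5 (-1.11) and Eif5a (-1.05) fell, while Eif4ebp1, which restrains cap-dependent translation, rose (1.64), as did the elongation factors Eef2 (0.71) and Eef1a1 (0.60).

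Tubulins, the cytosolic chaperonin with prefoldin, and proteasome subunits were lower as well. All 10 tested tubulin genes fell for the mean of guides (median -0.86, camera adjusted p = 2.22e-13), among them Tuba4a (-1.26) and Tubb6 (-1.15), with the caveat that close copies share reads. Of the 14 genes of the chaperonin that folds tubulin and actin and of its partner prefoldin, 12 fell and 2 rose (median -0.55, camera adjusted p = 4.05e-10), with Cct3 at -0.82 and Cct6a at -0.79, and Pfdn5 at 0.34. Of 29 proteasome subunits 28 fell (median -0.39, camera adjusted p = 8.96e-14), with Psmd1 at -0.83 and Psmd3 at -0.77, and Psmb5 was not called (-0.09, edgeR adjusted p = 0.0788). With an estimated correlation the adjusted p of these 3 lists was 0.00168, 0.0110 and 0.0119, and that of the translation factors 0.00840.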
